A study of Mus musculus with 27 samples.

How the data were processed

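The series holds 27 arrays of total RNA from TAMH cells. Per the labels' protocols, cells were grown to confluence in serum-free medium, dosed with APAP or AMAP at 2 mM or with control medium, and harvested after 2, 6 or 24 h. RNA was extracted with Trizol and purified on columns, and hybridised to Affymetrix Mouse Gene 1.0 ST arrays at a core facility. Per the submitters' processing notes, the arrays were processed with RMA in Affymetrix Expression Console 1.1. The deposited table gives 1 log2 value per probe set and array, per the labels a product of RMA, with no replicates pooled. The log base was read from the range of the values, as scanner files were not analysed here. Detection calls were not analysed either, and the annotation level of the summarisation is not stated. No genome build is named by the files, so no coordinates are given.

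The table holds 35557 probe sets. The annotation table covers 23410 of them, of which 21789 carry a single gene symbol and 1621 carry several, and 12147 carry none. Probe sets with a single symbol were kept, and for the 999 genes with more than 1 the probe set with the highest mean over all arrays was used, which left 19938 genes. Symbols were taken from the annotation as given, with no value changed and no filter on dim genes. The values were used as deposited, without further normalization.

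Groups were formed from treatment and time. A linear model with 9 group means was fitted to all 27 arrays with limma 3.58.1 in R 4.3.3, which left 18 residual degrees of freedom, and the variances were moderated with eBayes (prior degrees of freedom 7.3). Contrasts compared each compound with control and with the other compound at the same time, control cultures between times, and the effect of a compound between times. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, and all tests were two-sided. The comparisons, the gene lists, the panel, the rule for naming genes and the first set of alternatives were fixed before the data were examined. By that rule the named genes were the 6 largest increases and 6 largest decreases among called genes with all 3 arrays of 1 group above all 3 of the other and a mean log2 value of at least 6 in the higher group. They also included up to 4 members of each list with the smallest p and a panel of 26 genes, of which 22 were matched. For contrasts between times the 3 largest changes each way were named.

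In total 34 gene lists with 832 entries covered stress signalling, cell cycle, metabolism, liver function and cell type markers, and 764 entries were matched by symbol or synonym. Of these, 2 were matched by a synonym to another gene than the one meant, the acute phase entry C3 to Olfr48 and the hepatocyte marker Serpina1a to Serpina1d. Both stayed in the lists, and leaving them out, an alternative added after the data were seen, changed none of 306 list calls in the 9 treatment comparisons. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move on balance one way. Adjusted p values of lists are over the lists within a contrast. Members called are given over all genes tested and adjusted over the list alone. Intervals of differences are 95% intervals of the limma model. Intervals of medians over a set of genes are bootstrap intervals that resample genes, so they leave out the spread between arrays. The agreement between compounds was compared with 100 simulated sets of unchanged groups that shared their controls, since 3 control arrays cannot be split into groups of at least 2 arrays.

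Whether the numbers 30, 31 and 32 pair arrays across groups was tested by correlating, across genes, the deviations of arrays from their group means. Numbers were taken to pair the arrays of a comparison where the correlation was at least 0.1 for each number, which held for 5 of 9 comparisons between treatments, and 23 of 27 arrays correlated best with arrays of their own number. The model has no block for the number, which was tried as a fixed and as a random block (consensus correlation 0.041).

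The pipeline was tested on simulated data with the same layout, in which known changes of 3 sizes were added to 67, 67 and 66 of 19938 genes. Over the 9 treatment comparisons, 74.6% to 91.0% of changes of 0.5 log2 units, 98.5% to 100.0% of changes of 1 unit and 100.0% of changes of 2 units were recovered, with 5 to 16 false calls per comparison. Alternatives covered the replicate number as a block, the arrays in the model, the variance prior, array weights, scaling, dim genes, the choice of probe set, a 2-fold minimum, and leaving out each replicate number in turn. Leaving out single arrays, a block within each time, and leaving out arrays that stood apart on principal components were added after the data were seen. The first 4 components held 22.4%, 11.6%, 8.4% and 7.6% of the variance. Arrays of number 32 at 6 h stood apart on the fourth component, with scores of 18.9 (AMAP), 16.8 (APAP) and 11.1 (control), and APAP array 31 at 24 h on the first, with a score of 31.4. Where a group is left with few arrays, the lone or paired arrays are assumed to vary like the other groups.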

Results

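Gene expression was measured in TAMH cells, a hepatocyte line derived from mice that carry a transforming growth factor alpha transgene. The cultures received acetaminophen (APAP) at 2 mM, its regioisomer AMAP at 2 mM, or control medium, and were harvested after 2, 6 or 24 h. APAP carries its ring hydroxyl group in the para position and AMAP carries it in the meta position. Each of the 9 combinations of treatment and time holds 3 arrays, 27 in all, and the 3 arrays of a group bear the numbers 30, 31 and 32. The labels give cell passages between 25 and 35 and 2 dishes per treatment, so the numbers may be passages. They do not say so, nor whether the arrays came from separate cultures, and the tests measure the spread between these samples. The number of arrays limits the precision, and the median standard error of a difference between groups was 0.10 on the log2 scale. The deposited values span medians of 6.92 to 7.07 across arrays, and replicate arrays correlated with r between 0.992 and 0.997 across genes, which are not independent replicates.

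Hepatocyte markers gave bright signals in the control cultures, though signals of different probe sets do not measure relative amounts. Albumin (Alb) had a mean of 13.68 ± 0.09 (SD) on the log2 scale, and the 27 hepatocyte markers lay at a median percentile of 93.6 among all genes. The 17 macrophage and leukocyte markers lay at 24.2 and the 12 endothelial markers at 28.0. The 20 fibroblast and stellate cell markers lay at 41.6, with vimentin (Vim) at 12.96, fibronectin (Fn1) at 12.48 and decorin (Dcn) at 12.02 on the log2 scale. The 9 biliary and progenitor cell markers lay at 71.4.

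**Figure D1:**
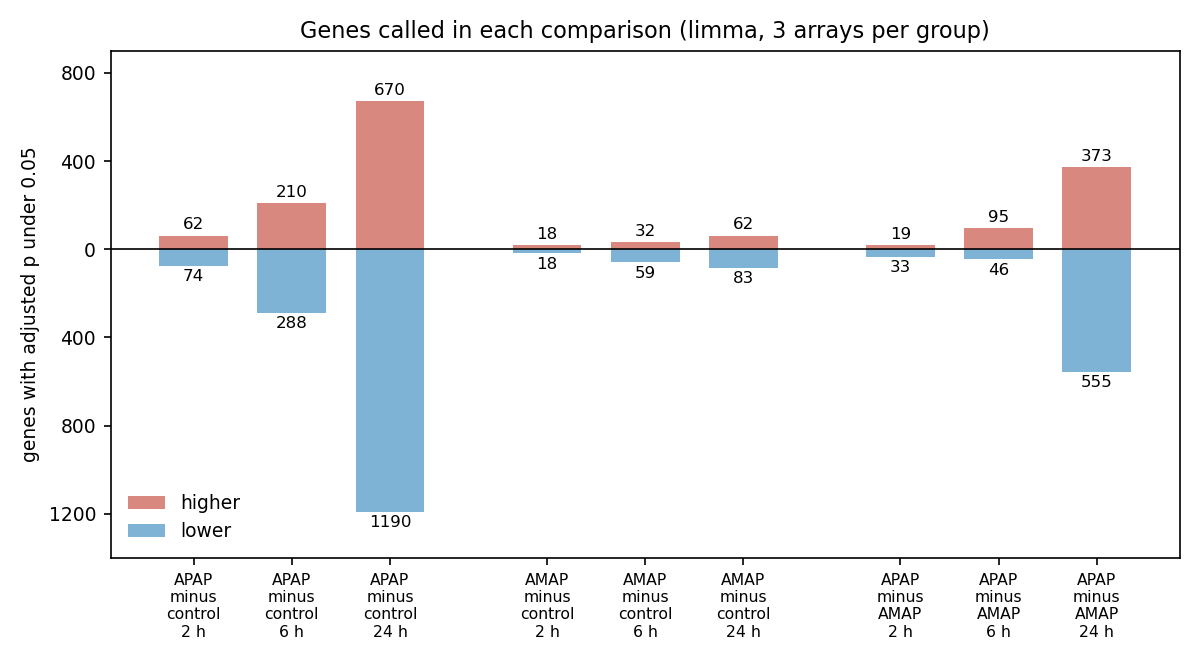
Genes called in each comparison (limma, adjusted p under 0.05, 3 arrays per group), with the number of higher genes drawn above 0 and of lower genes drawn below 0. APAP against control gave 136, 498 and 1860 genes at 2, 6 and 24 h, and AMAP against control gave 36, 91 and 145.

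By its title, the study asks how acetaminophen affects MAP kinase signalling, and the first question is what APAP changed against control at each time. At 2 h, APAP raised immediate early genes, the transcription factors and regulators that respond within minutes to growth and stress signals. Atf3, a stress-induced transcription factor, rose by 1.80 ± 0.24 on the log2 scale (3.48-fold, adjusted p = 6.92e-05). Egr1 (2.83-fold), the antiproliferative gene Btg2 (1.38 ± 0.12), Jun (1.33 ± 0.21) and Ier2 (1.01 ± 0.14) rose with it, as did Fos (0.81 ± 0.12) and the mRNA decay factor Zfp36 (0.86 ± 0.11). Values after ± are standard errors of the difference, with 3 arrays in each group. For the genes given as the largest changes, all 3 arrays of 1 group lay above all 3 of the other. Of 24 immediate early genes measured, 7 rose and 0 fell, 13 and 1 adjusted over the list alone (median 0.27, camera adjusted p = 5.69e-17).

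Targets of the tumour suppressor p53 were also higher at 2 h. The listed Cdkn1a, Bax and Gdf15 were unmatched and not tested, and Btg2 is in both this list and that of immediate early genes. Of 22 measured, 5 rose and 0 fell, 11 and 0 adjusted over the list alone (median 0.25, camera adjusted p = 1.69e-16). They included Mdm2 (0.70 ± 0.14), the ubiquitin ligase that degrades p53, the kinase Plk2 (1.02 ± 0.20) and the DNA repair nuclease Ercc5 (0.48 ± 0.10). Among genes of the amino acid and stress response driven by ATF4, 3 of 25 rose, namely the glutathione-degrading enzyme Chac1 (0.78 ± 0.14), Sesn2 (0.83 ± 0.16) and Ddit3 (0.76 ± 0.16), and 5 and 0 adjusted over the list alone. That list had camera adjusted p = 5.95e-06, and adjusted p = 0.625 with an estimated correlation. Gadd45a, which acts upstream of the stress kinases, rose by 0.80 ± 0.18, whereas the MAP kinase phosphatase Dusp1 had 0.76 ± 0.18 with adjusted p = 0.0526.

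The largest decreases at 2 h were in replication-dependent histones, whose mRNAs are made during DNA synthesis. H2ac4 fell from a mean of 8.91 to 6.41 (adjusted p = 4.86e-08), and its value with APAP lay below the array medians, so that a floor of the signal was not excluded and no fold is given. H2bc3 (-2.02 ± 0.18), H2bc14 (-1.72 ± 0.16), H1f5 (-1.62 ± 0.18), H2ac15 (-1.45 ± 0.12) and H2bc18 (-1.27 ± 0.16) fell as well. Of the 10 histone genes in the fixed list, 7 fell and 0 rose, also adjusted over the list alone (median -1.06, camera adjusted p = 4.51e-31). Histone genes form a multigene family with similar sequences, so the value of any single member is uncertain. Of 33 genes of mitosis, the motor protein Cenpe (-0.63 ± 0.13) and the cytokinesis factor Ect2 (-0.43 ± 0.10) fell, and 21 fell adjusted over the list alone (median -0.37). This list had camera adjusted p = 1.11e-24, and adjusted p = 0.222 with an estimated correlation. The calls of the histone, immediate early and p53 lists held with an estimated correlation (adjusted p = 4.02e-04, 0.0087 and 0.0087).

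In total, 62 genes rose and 74 fell with APAP at 2 h among 19938 tested with limma, and 17 of the 136 changed at least 2-fold. The numbers pair the arrays in this comparison, and with the replicate number as a block 214 genes were called. The count was 74 without APAP array 31 and 82 without control array 32, and with all arrays of number 31 left out Jun, Ier2, Ddit3, Gadd45a, Sesn2, Chac1, Cenpe, Ect2 and Ercc5 were no longer called, nor were Fos, Plk2 and Mdm2 without number 32.

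At 6 h p53 targets were higher with APAP. Of 22, 13 rose and 0 fell, 19 and 0 adjusted over the list alone (median 0.47, camera adjusted p = 4.92e-32, adjusted p = 5.53e-04 with an estimated correlation). Among them were the death receptor Fas (0.82 ± 0.10), the BH3-only protein Pmaip1 (0.74 ± 0.10), Mdm2 (0.91 ± 0.14) and Btg2 (1.00 ± 0.12). Atf3 rose by 1.97 ± 0.24 (adjusted p = 2.33e-05) and Jun by 1.27 ± 0.21, within a list of immediate early genes of which 4 of 24 rose, 6 adjusted over the list alone (median 0.20, camera adjusted p = 4.52e-07). The call of that list was lost, with adjusted p = 0.182 with an estimated correlation. Other large increases were the alpha-arrestin Arrdc3 (1.36 ± 0.18), the Myb family member Mybl1 (1.27 ± 0.12), Strip2 (1.14 ± 0.10) and Gadd45a (1.14 ± 0.18).

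Genes of mitosis fell at 6 h. Of 33, 24 fell and 0 rose, 26 and 0 adjusted over the list alone (median -0.60, camera adjusted p = 2.59e-38), with adjusted p = 0.0793 with an estimated correlation. The spindle checkpoint kinase Bub1b fell by 1.25 (adjusted p = 1.55e-04), and the mitotic kinase Plk1 (-1.24 ± 0.22), the centromere protein Cenpf (-1.18 ± 0.17) and the spindle factor Tpx2 (-0.83 ± 0.12) fell too. Of 33 genes of DNA replication and G1/S, 4 rose and 0 fell, 7 and 1 adjusted over the list alone, among them E2f1 (0.43 ± 0.08) and cyclin E1 (Ccne1, 0.59 ± 0.12). That list had camera adjusted p = 1.65e-06, and adjusted p = 0.617 with an estimated correlation. Histones were lower with 6 of 10 called, 8 adjusted over the list alone (median -0.52, adjusted p = 0.0277 with an estimated correlation), including H1f5 (-1.28 ± 0.18) and H2ac4. The H2ac4 mean with APAP again lay below the array medians, so no size is given. Of 25 ATF4 targets 4 rose, 7 adjusted over the list alone, including Ddit3 (1.07 ± 0.16) and Sesn2 (0.98 ± 0.16), with adjusted p = 0.440 with an estimated correlation. Of 35 MAP kinase cascade components, Gadd45a, Gadd45g (0.54 ± 0.12), the kinase Mapkapk3 (0.55 ± 0.12) and 1 more rose and Map2k6 (-0.49 ± 0.10), a kinase upstream of p38, fell, 6 and 5 adjusted over the list alone (camera adjusted p = 0.111).

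In total, 210 genes rose and 288 fell at 6 h, 264 and 232 after quantile normalization, and 19 of the 498 changed at least 2-fold. The count was 286 without APAP array 31, 316 without APAP array 32, 296 without control array 30 and 265 without control array 31. Only the 6 arrays of the comparison, fitted alone, called 229 genes, and with all arrays of number 31 left out Ddit3, H2ac4, E2f1, Ccne1 and Map2k6 were no longer called, nor were Sesn2, Mdm2 and Gadd45g without number 32 and Mapkapk3 without number 30.

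**Figure D2:**
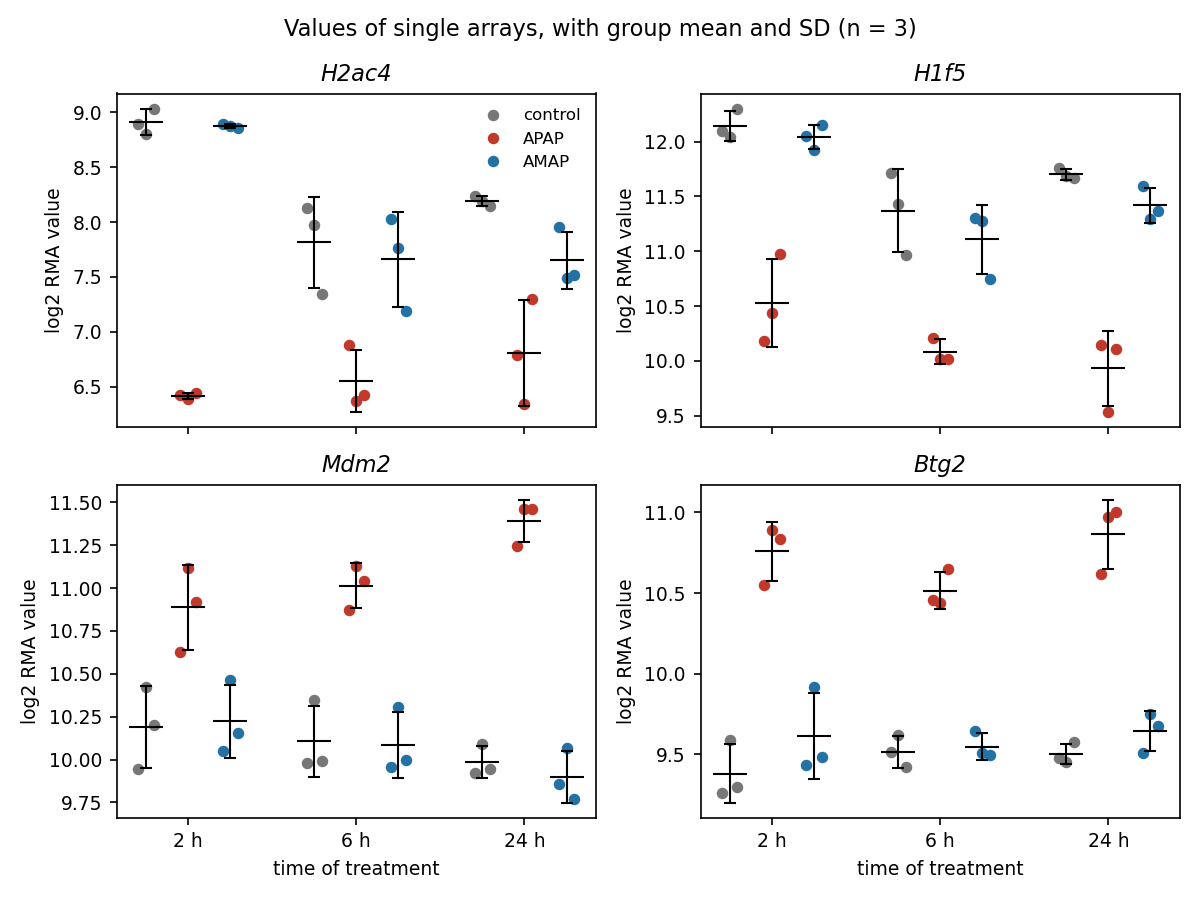
Log2 RMA values of H2ac4, H1f5, Mdm2 and Btg2 against time of treatment, with 1 point per array and the mean and SD of each group of 3 arrays; the value axes do not start at 0. At each time the 3 APAP arrays lay below the 3 control arrays for H2ac4 and H1f5 and above them for Mdm2 and Btg2.

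At 24 h APAP raised p53 targets, with 16 of 22 called higher and 0 lower, 19 and 0 adjusted over the list alone (median 0.65, camera adjusted p = 1.08e-24, adjusted p = 0.0024 with an estimated correlation). Mdm2 rose by 1.40 ± 0.14 (adjusted p = 3.63e-07), and Btg2 (1.36 ± 0.12), Ercc5 (1.04 ± 0.10) and the membrane protein Perp (0.77 ± 0.08) rose too. Immediate early genes were higher as a list, with 8 of 24 called higher and 0 lower, 12 and 0 adjusted over the list alone (median 0.23, camera adjusted p = 1.18e-07, adjusted p = 0.153 with an estimated correlation). They included Atf3 (2.00 ± 0.24, 4.01-fold, adjusted p = 6.63e-06) and Jun (1.68 ± 0.21). The other largest increases were Arrdc3 (2.02 ± 0.18), Pm20d1, which makes N-acyl amino acids (1.68 ± 0.10), Mybl1 (1.47 ± 0.12) and the acute phase protein Serpina3n (1.43 ± 0.33).

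Sterol and lipid synthesis genes fell with APAP at 24 h. Of 19 genes of cholesterol synthesis, 15 fell and 1 rose, 18 and 1 adjusted over the list alone (median -0.65, camera adjusted p = 8.61e-18, adjusted p = 0.114 with an estimated correlation). The isoprenoid enzyme Fdps fell by 0.74 (adjusted p = 7.58e-07), and squalene synthase (Fdft1, -0.84 ± 0.12), the sterol carrier Stard4 (-0.69 ± 0.08) and the sterol enzyme Nsdhl (-0.68 ± 0.08) fell, while Tm7sf2, a sterol reductase, rose by 0.32 ± 0.10. Of 20 genes of fatty acid synthesis and storage, 9 fell, 9 lower and 1 higher adjusted over the list alone (median -0.18, camera adjusted p = 2.65e-04, adjusted p = 0.427 with an estimated correlation). The lipogenic transcription factor Srebf1 (-0.55 ± 0.08), the elongase Elovl6 (-0.83 ± 0.13) and the desaturase Scd1 (-0.63 ± 0.11) were among them. In the list of PPAR alpha targets and fatty acid oxidation 7 of 20 rose and 0 fell, 8 and 0 adjusted over the list alone (median 0.31, camera adjusted p = 7.67e-05, adjusted p = 0.423 with an estimated correlation), led by the pyruvate dehydrogenase kinase Pdk4 (0.94 ± 0.13).

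Lists of histones, ribosome biogenesis and mitosis were lower at 24 h as well. Histones fell in 6 of 10 genes, 7 lower and 1 higher adjusted over the list alone (median -0.66, adjusted p = 0.114 with an estimated correlation), with H1f5 falling by 1.77. H2ac4 was lower too, with no size given, as its mean with APAP lay below the array medians. Genes of ribosome biogenesis fell in 14 of 30 cases, 19 adjusted over the list alone (median -0.29, camera adjusted p = 1.69e-11, adjusted p = 0.402 with an estimated correlation), for example the pseudouridine synthase Dkc1 (-0.58 ± 0.12). Mitosis genes fell in 11 of 33 cases, 18 adjusted over the list alone (median -0.31, adjusted p = 0.427 with an estimated correlation), Bub1b by 1.04. Besides histones, the largest decreases were the thyroxine-binding globulin Serpina7 (-1.54 ± 0.32), the transporter Slc17a1 (-1.16 ± 0.24) and the monooxygenase Fmo1 (-1.13 ± 0.18). Of 27 hepatocyte markers, 1 fell (Foxa2, -0.29 ± 0.08) and 0 rose, and 0 were called adjusted over the list alone.

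For MAP kinase signalling genes, 5 of 35 MAP kinase cascade components rose and 5 fell at 24 h, also adjusted over the list alone (camera adjusted p = 0.655). Gadd45b (0.92 ± 0.16) and Gadd45g (0.72 ± 0.12) rose and Map2k6 fell by 0.95. Of 17 MAP kinase phosphatases and feedback inhibitors, Dusp8 (0.54 ± 0.11) and Dusp1 (0.64 ± 0.18) rose and Dusp9 (-0.50 ± 0.09) fell, 3 and 4 adjusted over the list alone (camera adjusted p = 0.888). Of 36 NRF2 targets and glutathione genes, which respond to electrophiles, 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.888). Epoxide hydrolase 1 (Ephx1, 0.74 ± 0.10) rose and transketolase (Tkt, -0.44 ± 0.08) fell, while heme oxygenase 1 (Hmox1, 0.20 ± 0.10, adjusted p = 0.2633), Nqo1 (0.02 ± 0.13), Gclc (0.21 ± 0.11) and Srxn1 (0.10 ± 0.11) did not pass the test.

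In total, 670 genes rose and 1190 fell at 24 h, 394 and 1808 with the arrays centred on their medians, and 37 of the 1860 changed at least 2-fold, 24 higher and 13 lower. The count was 1090 without APAP array 31, which stood apart on the first principal component, and 1219, 1044 and 1214 without control arrays 30, 31 and 32. With all arrays of number 31 left out, Serpina3n, Serpina7, Slc17a1, Tkt, Foxa2 and Dkc1 were no longer called, nor was Dusp1 without number 30 or 32.

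The second question is what the regioisomer AMAP changed against control. At 2 h AMAP raised Chac1 (0.86 ± 0.14, adjusted p = 0.0063), Strip2 (0.76 ± 0.10), the zinc finger gene Zfp119a (0.74 ± 0.13) and the chaperone cofactor Dnajb9 (0.56 ± 0.11). It lowered the homeobox gene Dlx1 (-0.80 ± 0.10), the epithelial transcription factor Ehf (-0.78 ± 0.14) and the matricellular protein gene Ccn4 (-0.63 ± 0.13). Of 24 immediate early genes 0 were called with limma, 5 higher and 1 lower adjusted over the list alone (median 0.13, camera adjusted p = 8.47e-04, adjusted p = 0.695 with an estimated correlation). Of 22 p53 targets and of 10 histones 0 were called, with medians of 0.00 and 0.07. Atf3 had 0.45 ± 0.24 with adjusted p = 0.7808 and Jun had 0.15 ± 0.21 with adjusted p = 0.9913.

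In total, 18 genes rose and 18 fell with AMAP at 2 h, 1356 passed an unadjusted p of 0.05, and 0 of the 36 changed at least 2-fold. The 6 arrays fitted alone with limma called 0 genes, with 1274 at an unadjusted p under 0.05. The count was 9 without AMAP array 30, 22 without AMAP array 32, and 16, 9 and 22 without control arrays 30, 31 and 32, and each gene named here lost its call without the arrays of number 31.

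At 6 h AMAP raised the magnesium transporter gene Cnnm4 (0.76 ± 0.09, adjusted p = 3.19e-05), Strip2 (0.78 ± 0.10) and Hexim1, an inhibitor of transcription elongation (0.70 ± 0.14). The largest decreases were Ms4a6b (-1.05 ± 0.13), the leukotriene receptor Cysltr1 (-0.84 ± 0.14), the apolipoprotein gene Apon (-0.83 ± 0.13), the innate DNA sensor adaptor Sting1 (-0.82 ± 0.12), Tnfsf18 (-0.81 ± 0.16) and thrombospondin 1 (Thbs1, -0.81 ± 0.17). Of the 24 immediate early genes, 22 p53 targets, 33 mitosis genes and 10 histones, 0 were called with limma, and their medians lay between -0.064 and -0.005. In total 32 genes rose and 59 fell, 1889 passed an unadjusted p of 0.05, and 1 of the 91, Ms4a6b, changed at least 2-fold. The numbers pair the arrays, and with the replicate number as a block 200 genes were called, whereas the 6 arrays fitted alone called 5. The count was 28 without AMAP array 30 or 31, 28, 54 and 31 without control arrays 30, 31 and 32, and without the arrays of number 30 Strip2, Hexim1, Cysltr1, Sting1, Tnfsf18 and Thbs1 lost their calls, as did Apon without number 31 or 32.

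The largest increases with AMAP at 24 h were the acetyl-CoA synthetase Acss2 (0.86 ± 0.18), the GABA transaminase Abat (0.81 ± 0.18), the valine catabolic enzyme Aldh6a1 (0.72 ± 0.16), Txndc16 (0.71 ± 0.12), Tm7sf2 (0.69 ± 0.10, adjusted p = 8.11e-04) and the cation channel Trpm4 (0.62 ± 0.14). AMAP lowered Tnip3, an inhibitor of NF-kB signalling (-1.32 ± 0.23), the cornified envelope gene Sprr1a (-1.14 ± 0.24), the gap junction protein Gja1 (-1.08 ± 0.15) and the chemotactic factor Lect2 (-1.02 ± 0.24). Of 36 NRF2 targets and glutathione genes, the glutathione transferase Gstm1 (0.42 ± 0.09) and the carbonyl reductase Cbr1 (0.39 ± 0.09) rose, 7 and 0 adjusted over the list alone (median 0.08, camera adjusted p = 0.0016, adjusted p = 0.503 with an estimated correlation). Of 19 cholesterol synthesis genes 1 rose and 0 fell, also adjusted over the list alone (median 0.12, camera adjusted p = 5.00e-04, adjusted p = 0.724 with an estimated correlation). Transforming growth factor beta 1 (Tgfb1) fell by 0.66 and the acute phase genes Orm1 (-0.73 ± 0.16) and Lcn2 (-0.64 ± 0.15) fell. No panel gene of the stress and drug response, Atf3, Jun, Ddit3 and Hmox1 included, was called for AMAP at any time, and with an estimated correlation no list was called.

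In total 62 genes rose and 83 fell with AMAP at 24 h, 33 and 92 with the arrays centred on their medians, and 5 of the 145 changed at least 2-fold. The count was 37 without AMAP array 31, 89 without AMAP array 32, and 69, 35 and 56 without control arrays 30, 31 and 32. Among the genes named here Tgfb1 alone kept its call without each number in turn, Tm7sf2 losing it without number 31 and Gja1 without number 30.

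**Figure D3:**
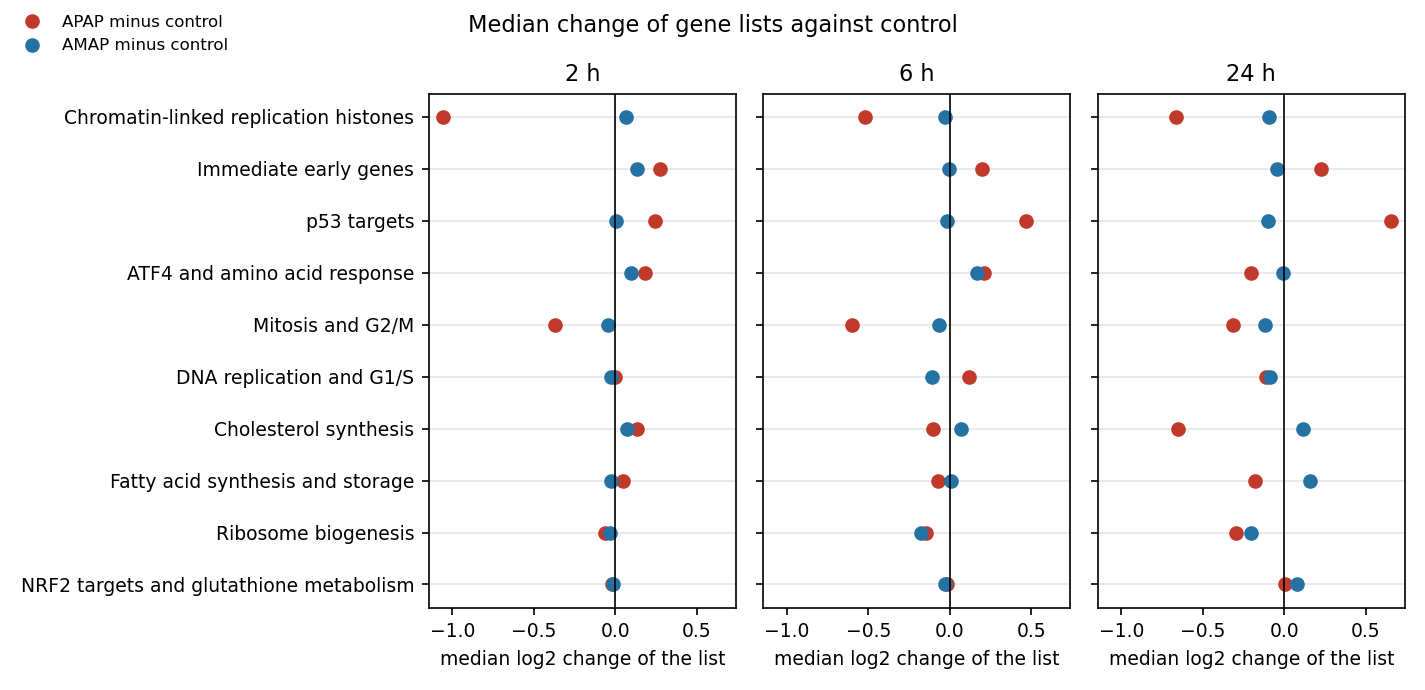
Median log2 change of gene lists against control for APAP and AMAP at 2, 6 and 24 h, with 1 point per list and compound. The p53 targets had medians of 0.25, 0.47 and 0.65 with APAP and of 0.00, -0.02 and -0.10 with AMAP.

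The third question is where the regioisomers differed at the same dose and time. At 2 h Atf3 (1.35 ± 0.24, adjusted p = 0.0053), Jun (1.18 ± 0.21), Btg2 (1.14 ± 0.12), Egr1 (1.06 ± 0.16), Fos (0.69 ± 0.12) and Dusp1 (0.85 ± 0.18) were higher with APAP. Histones were lower with APAP, H2bc3 by -1.89 ± 0.18, with 7 of 10 called, 9 adjusted over the list alone (median -1.05, adjusted p = 5.22e-05 with an estimated correlation). H2ac4 was lower as well (limma adjusted p = 9.12e-08), with no size given, since a floor of its signal with APAP was not excluded. Of 22 p53 targets 4 were higher with APAP, 12 adjusted over the list alone (median 0.32, adjusted p = 0.0156 with an estimated correlation), among them Mdm2 (0.66 ± 0.14). Of 24 immediate early genes 6 were higher, 7 adjusted over the list alone, with adjusted p = 0.0743 with an estimated correlation. Of 33 mitosis genes 0 were called with limma, 21 lower adjusted over the list alone (median -0.36, camera adjusted p = 1.40e-27), with adjusted p = 0.166 with an estimated correlation. Chac1, higher than control with both compounds, differed between them by -0.08 (95% interval -0.37 to 0.21), and Dnajb9 by 0.03 (-0.20 to 0.26). For Ddit3 the interval ran from -0.23 to 0.45 and for Gadd45a from -0.20 to 0.54, so that neither gene was shown to differ between the compounds.

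At 6 h, 14 of 22 p53 targets were higher with APAP than with AMAP and 0 lower, 19 and 0 adjusted over the list alone (median 0.57, adjusted p = 7.92e-05 with an estimated correlation). Fas differed by 0.92 ± 0.10 (adjusted p = 9.27e-06), Mdm2 by 0.93 ± 0.14 and Btg2 by 0.97 ± 0.12. Atf3 differed by 1.84 ± 0.24, Jun by 1.12 ± 0.21, cyclooxygenase 2 (Ptgs2) by 1.28 ± 0.23 and the thioredoxin-binding protein Txnip by 1.18 ± 0.23, and 3 of 24 immediate early genes were higher, 10 adjusted over the list alone (adjusted p = 0.0187 with an estimated correlation). Mitosis genes were lower with APAP in 12 of 33 cases, 24 adjusted over the list alone (median -0.54, adjusted p = 0.0357 with an estimated correlation), Cenpf by -1.24 ± 0.17 and Bub1b by -1.03 ± 0.18. Genes of DNA replication and G1/S were higher with APAP in 5 of 33 cases, 18 adjusted over the list alone (median 0.23, adjusted p = 0.0339 with an estimated correlation), including Ccne1 (0.69 ± 0.12) and the primase Prim1 (0.44 ± 0.09). Histones were lower in 5 of 10 cases, 8 adjusted over the list alone (median -0.56, adjusted p = 0.0056 with an estimated correlation). Cnnm4 and Ms4a6b, called against control for both compounds, differed by 0.00 (-0.17 to 0.18) and -0.01 (-0.28 to 0.26).

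At 24 h, 19 of 22 p53 targets were higher with APAP than with AMAP and 0 lower, also adjusted over the list alone (median 0.81, camera adjusted p = 3.55e-36, adjusted p = 2.45e-04 with an estimated correlation). Mdm2 had means of 11.39 ± 0.12 with APAP and 9.90 ± 0.15 with AMAP (SD), a difference of 1.49 ± 0.14 (2.81-fold, adjusted p = 1.15e-07), and Fas differed by 1.07 ± 0.10. The growth factor Csf2 (1.81 ± 0.32), Serpina3n (1.55 ± 0.33), the solute carrier Slc4a11 (1.51 ± 0.14) and the glutamate receptor subunit Gria3 (1.46 ± 0.12) were among the largest increases, with Atf3 at 1.86 ± 0.24 and Jun at 1.43 ± 0.21. Of 24 immediate early genes 10 were higher, 13 adjusted over the list alone (adjusted p = 0.0321 with an estimated correlation). Cholesterol synthesis genes were lower with APAP in 18 of 19 cases, also adjusted over the list alone (median -0.75, camera adjusted p = 1.81e-32, adjusted p = 0.0175 with an estimated correlation). Lanosterol synthase (Lss) differed by -1.07 ± 0.17 (adjusted p = 1.86e-04), Nsdhl by -0.86 ± 0.08, Dhcr7 by -0.93 ± 0.16 and HMG-CoA synthase 1 (Hmgcs1) by -0.91 ± 0.16. Fatty acid synthesis genes were lower in 11 of 20 cases, 12 lower and 1 higher adjusted over the list alone (median -0.42, camera adjusted p = 3.88e-13, adjusted p = 0.0753 with an estimated correlation), with Scd2 at -0.73 ± 0.08 and Scd1 at -0.79 ± 0.11. Orm1, lower than control with both compounds, differed by 0.03 (-0.29 to 0.35).

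**Figure D4:**
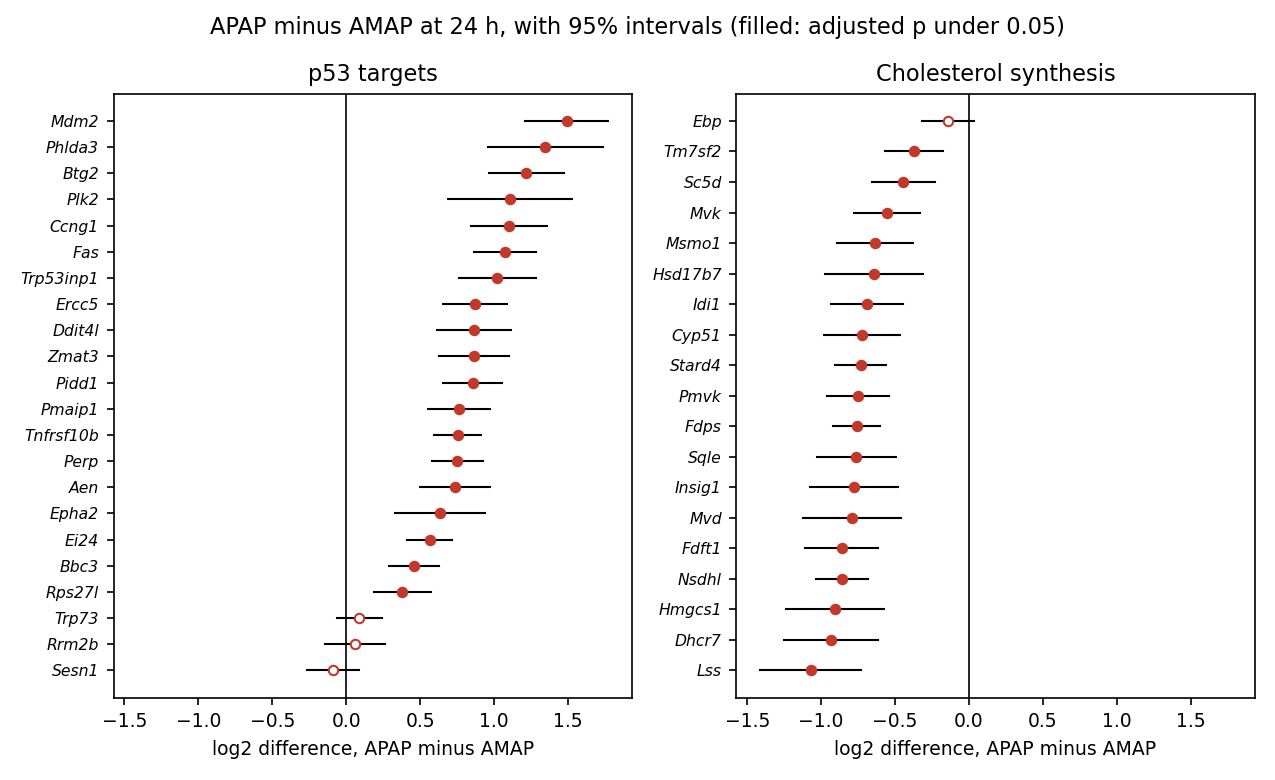
Log2 difference between APAP and AMAP at 24 h for the 22 p53 targets and the 19 cholesterol synthesis genes, with 95% intervals as lines and filled points for adjusted p under 0.05. Of the p53 targets 19 were higher with APAP, and of the cholesterol synthesis genes 18 were lower.

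Between the compounds, 19 genes were higher and 33 lower with APAP at 2 h, 95 and 46 at 6 h (103 and 29 with the arrays centred on their medians), and 373 and 555 at 24 h (269 and 705 when centred). Of those at 24 h that differed at least 2-fold, 39 were higher and 2 lower with APAP. At 2 h the 52 genes became 80 without AMAP array 32, 28 without APAP array 31 and 34 without APAP array 32. At 6 h the 141 genes became 51 and 82 without AMAP arrays 30 and 31, 84, 92 and 70 without APAP arrays 30, 31 and 32, and 28 when the 6 arrays were fitted alone. At 24 h the 928 genes became 507 and 575 without AMAP arrays 30 and 32, and 314 when the 6 arrays were fitted alone. Without the arrays of number 31, Atf3, Jun, Egr1 and Fos at 2 h and Jun, Ptgs2, Txnip, Bub1b, Ccne1 and Prim1 at 6 h were no longer called different, and without number 32 Dusp1 and Mdm2 at 2 h and Mdm2 at 6 h were not, nor at 24 h Serpina3n and Hmgcs1 without number 30.

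Of the 136, 498 and 1860 genes called for APAP at 2, 6 and 24 h, AMAP was called in the same direction for 23, 70 and 86. The compounds themselves differed for 39, 93 and 577 of them, and for the other 97, 405 and 1283 no difference was shown. These tallies use the model without a block, although the numbers pair APAP and AMAP arrays at 6 and 24 h. Among all genes, a block within each time called 301 and 1896 different between the compounds there, against 141 and 928 without it. At 24 h 4 genes were called in opposite directions, chosen here after their values were seen, namely the drug efflux pump Abcb1b (0.51 ± 0.14 with APAP and -0.78 ± 0.14 with AMAP), the carboxylesterase Ces2e (0.83 and -0.40), Gria3 (0.98 and -0.48) and the protease St14 (0.42 and -0.40). Both compounds share their control arrays, which alone makes their changes correlate. The correlations of 0.482, 0.594 and 0.481 compare with 0.499 (0.479 to 0.521) in 100 simulated sets of unchanged groups against shared controls. At 2 and 24 h they lay within that range, but leaving out each number in turn gave 0.397 to 0.578 and 0.414 to 0.538, on both sides of it. The simulated groups hold no real changes, whereas changes with APAP alone widen the spread and lower the correlation. A correlation within the simulated range is therefore no measure of whether a response is shared. The covariance of the changes was above that simulation at each time, by 0.0020, 0.0066 and 0.0081, against a simulated 0.0060 (0.0057 to 0.0064). That simulation drew every gene and array independently, without deviations shared by arrays of a number. At 24 h the numbers pair APAP with AMAP arrays (correlations of 0.21 to 0.47) but neither with control, which alone can raise the covariance. At 24 h the excess by itself therefore does not show a shared response. At 6 h that reason does not hold, since the numbers pair all groups there. Correlations were 0.19 to 0.40 for APAP with control, 0.19 to 0.37 for AMAP with control and 0.25 to 0.43 between compounds. The 6 h covariance and correlation both lay above the simulated ranges. At 2 h the numbers pair only APAP with control, so the reason does not hold there either. Whether a shared response gave the excess at 2 and 6 h was not tested. For independent lists 0.1 genes higher and 0.1 lower would be shared at 2 h, 0.3 and 0.9 at 6 h, and 2.1 and 5.0 at 24 h, against 12 and 11, 27 and 43, and 40 and 46 observed. That expectation leaves out the shared controls, so part of the excess may come from them. In 20 simulated sets of unchanged groups with the 24 h layout the highest number of shared calls was 0, which says little, since unchanged groups give few calls at all.

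The next comparison asks whether the effect of a compound differed between times. The APAP effect at 24 h differed from that at 2 h for 71 genes, 34 more positive and 37 more negative (19 and 53 with the arrays centred on their medians). Arrdc3 differed by 1.84 (adjusted p = 5.40e-04), the fibril-associated collagen Col12a1 by 1.34 and Pm20d1 by 1.304, while the early gene Egr1 (-0.98), the lipase Pnpla3 (-0.999) and the mevalonate pathway kinase Pmvk (-0.99) differed the other way. In the controls themselves Egr1 rose and Arrdc3 fell from 2 to 24 h, as given below. Their differences thus include change in the controls and do not show a change in the APAP cultures alone. Between 24 and 6 h the APAP effect differed for 2 genes, Col12a1 (1.28) and Ces2e (0.79), and for 5 and 2 genes after quantile normalization. For APAP between 6 and 2 h and for AMAP between 24 and 2 h, 0 genes were called with limma, with 680 and 937 at an unadjusted p under 0.05. With the replicate number as a block, AMAP between 24 and 2 h gave 7 genes, and with the block within each time it gave 29 and APAP between 6 and 2 h gave 3. The 71 and 2 genes of APAP became 187 and 12 with the block and 447 and 127 with the block within each time. Of the genes called for APAP at 6 h, 133 of 210 higher and 177 of 288 lower genes were called in the same direction at 24 h, with the control arrays of each time separate. Leaving out the arrays of number 30 left 0 genes for both APAP comparisons with 24 h (1058 and 832 at an unadjusted p under 0.05), and leaving out number 32 left 0 for 24 against 6 h (1448). The 71 genes became 34, 38 and 39 without control 24 h arrays 30, 31 and 32, 47, 32 and 32 without control 2 h arrays 30, 31 and 32, and 46, 26 and 43 without APAP 2 h arrays 30, 31 and 32. The 2 genes became 4 without APAP 24 h array 30, control 24 h array 30 or control 6 h array 32.

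Control cultures also changed with time. From 2 to 6 h Csf2 (1.70 ± 0.32, adjusted p = 0.0106), the chemokine Ccl20 (1.38 ± 0.26) and Ankrd1 (1.17 ± 0.22) rose, and the zinc exporter Slc30a1 (-1.30 ± 0.13), H2ac4 (-1.10 ± 0.21) and H1f1 (-1.06 ± 0.18) fell. From 2 to 24 h Ccl20 (1.61 ± 0.26), Csf2 (1.46 ± 0.32) and Egr1 (1.08 ± 0.16) rose, and H1f2 (-1.25 ± 0.22), Arrdc3 (-1.17 ± 0.18) and Tgfbr1 (-0.98 ± 0.16) fell. Histones fell in 7 of 10 cases by 6 h, 8 adjusted over the list alone (median -0.58, adjusted p = 0.0125 with an estimated correlation), and in 6 of 10 by 24 h, 10 adjusted over the list alone (median -0.63, adjusted p = 0.0249 with an estimated correlation). Of 26 NF-kB targets 3 rose by 6 h and 4 by 24 h, 8 and 10 adjusted over the list alone, with adjusted p = 0.238 and 0.334 with an estimated correlation. In total 88 genes rose and 53 fell by 6 h (44 and 57 with the arrays centred), and 102 rose and 125 fell by 24 h (63 and 120 when centred). The 141 genes became 73 and 27 without 2 h arrays 31 and 32, 72, 78 and 42 without 6 h arrays 30, 31 and 32, and 60 when the 6 arrays were fitted alone. The 227 became 43 and 33 without 2 h arrays 31 and 32, 25, 96 and 44 without 24 h arrays 30, 31 and 32, and 123 when the 6 arrays were fitted alone, and among the genes named here Slc30a1 alone kept its call without each number in turn.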

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

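The tests of RNA without a poly(A) tail and of matched random lists were set before their results were seen; the tests of bright and longer RNAs without a tail, histone classes, replacement histones, scaling, hepatocyte markers, single arrays and splits were chosen after the result was seen.

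Replication-dependent histone genes were lower with APAP than with control at 2 h, with a median of -0.91 over 29 genes, 20 of them called. Loss of RNA without a poly(A) tail is argued against by 54 small nucleolar RNA genes, whose median change was 0.081 (bootstrap 0.036 to 0.107), and 0.092 (0.057 to 0.119) for the 39 with a control mean of at least 8, and by 5 longer RNAs, Rn7sk (0.05 ± 0.08), Rmrp (0.04 ± 0.09), Rpph1 (0.03 ± 0.09), Terc (0.06 ± 0.08) and Rnu3a (0.21 ± 0.18), with control means of 13.80, 12.56, 12.76, 8.24 and 7.71. A single fallen transcript read by near-identical probe sets is argued against by the histone classes, 4 of 5 of which had a median under -0.5 (H1 -0.80, H2A -1.19, H2B -0.78, H4 -0.91, with H3 at -0.36). An offset left between the arrays is argued against by the median change of all genes, which was 0.012 in this comparison. A shift of all genes that RMA had already removed would not show in that median and was not tested. Quantile normalization left the histone median at -0.879. With so small a shift in values already processed by RMA, it could hardly have removed the fall and adds little. A candidate explanation that remains is slowed DNA synthesis with decay of histone mRNA. Under it replacement histone genes, made outside DNA synthesis, keep their level, and 7 of them had a median of -0.017. The interval of that median, -0.047 to 0.059, is a bootstrap over genes and leaves out the spread between arrays. Any cause confined to replication-dependent histones would leave the replacement genes unchanged too, so this test does not single out slowed synthesis. The list of DNA replication and G1/S genes had a median of -0.001 in this comparison, and DNA synthesis itself was not measured. Slowed synthesis is a hypothesis found and tested on the same arrays.

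Cholesterol synthesis genes were lower with APAP than with AMAP at 24 h, with a median of -0.75 over 19 genes. A general fall of bright probe sets on the APAP arrays is argued against by 10000 random lists matched for signal, among which the list lay at percentile 0.00 and the lowest random median was -0.26. A lower share of hepatocyte-like cells is argued against by a median of -0.042 over the hepatocyte markers. Its interval of -0.125 to 0.081 is a bootstrap over genes and leaves out the spread between arrays. A response of the sterol pathway that differs between the compounds may account for the pattern, as a hypothesis for which no direct measure of sterols was analysed here.

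More genes were called for APAP than for AMAP against control at 24 h, 1860 and 145. A single deviating array is argued against by the lowest APAP count with 1 array left out, 1044, which lies above the highest AMAP count, 103. For a narrower spread of values on the APAP arrays, the counts after quantile normalization were 1828 for APAP and 172 for AMAP. The values had already been processed by RMA, so that step could change little. These counts are thus weak evidence against a narrower spread. A larger response to APAP at this dose is a candidate explanation, untested on other cultures.

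The effect of APAP differed between 24 and 2 h for 71 genes, and a difference between times brought these results here. They included Arrdc3 (1.84, adjusted p = 5.40e-04), Col12a1 (1.34, 2.24e-04), Pm20d1 (1.304, 6.53e-05), Pnpla3 (-0.999, 0.0264), Pmvk (-0.99, 5.40e-04) and Egr1 (-0.98, 0.0454). The Arrdc3 and Egr1 differences include change in the controls, in which Arrdc3 fell and Egr1 rose over that span. Between 24 and 6 h the APAP effect differed for 2 genes, Col12a1 (1.28, 7.30e-04) and Ces2e (0.79, 3.64e-04). Of 100 splits of the arrays, 9 gave at least as many genes as the 71 (highest other split 722) and 14 at least as many as the 2 (highest other 1304). The highest split of each count kept all 3 APAP arrays labelled as treated at 24 h and 1 of 3 at the earlier time, so the APAP effect at 24 h was left in the contrast, a structure of the samples. Such splits are no clean test of chance, and whether chance gave either count is left open. For the AMAP effect between 24 and 2 h and the APAP effect between 6 and 2 h, with 0 genes each and 937 and 680 at an unadjusted p under 0.05 with limma, the splits test nothing, since any split gives at least 0 (highest other 16 and 163).

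For comparisons of 3 against 3 arrays there are 10 splits, so the share of splits with as many genes cannot fall below 0.1, and 1 of 10 gave as many genes in each case, the real split. Every other split mixes arrays of both groups with the real difference left in, which widens the spread of the changed genes. Low counts in those splits are thus no measure of the count without a difference. The real count and the highest other split were 136 and 0, 498 and 2, and 1860 and 0 for APAP against control at 2, 6 and 24 h. They were 36 and 0, 91 and 4, and 145 and 2 for AMAP, and 52 and 0, 141 and 0, and 928 and 99 for APAP against AMAP. They were 141 and 0 for control at 6 against 2 h and 227 and 0 for control at 24 against 2 h. In the comparisons whose numbers pair the arrays, splits that part all pairs gave at most 0 genes, and the 2, 4 and 99 came from splits that do not.

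Probe sets without a single gene symbol hold a signal that no comparison above uses. Of 13768 such probe sets, 57, 67 and 357 were called for APAP against control at 2, 6 and 24 h. For AMAP against control 4 and 8 were called at 6 and 24 h. Between APAP and AMAP 52, 37 and 192 were called at 2, 6 and 24 h.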

How the results depend on the processing

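Single-array, block-within-time, stood-apart and list-match settings were chosen after the data were seen, the other alternatives before; the cause of each shift was not tested. No value changed direction past its threshold. Of 367 called results of named genes 119 kept their call in every alternative; those lost numbered 129 with only the groups compared, 207, 185 and 120 without number 30, 31 and 32, 23 with the arrays centred and 17 after quantile normalization. Of 96 called list results 16 kept their call everywhere and 16 were called with an estimated correlation, and 67 lost their call with fry. The largest move of the median of all genes with scaling was from 0.018 to -0.044, for APAP against control at 24 h with the arrays centred. Signal over background was not analysed here, so a floor may also limit the sizes given for other decreases that end at low signals.

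Counts are given where they moved by more than 1.5 times. With the replicate number as a fixed block, APAP against control gave 214 genes at 2 h, AMAP against control 200 at 6 h and 345 at 24 h, control 271 (6 against 2 h) and 502 (24 against 2 h), the APAP effect 187 (24 against 2 h) and 12 (24 against 6 h), and the AMAP effect 7. As a random block the APAP effect gave 112 and 5. With only the groups compared, APAP gave 86, 229 and 957 at 2, 6 and 24 h, AMAP 0 (1274 at an unadjusted p under 0.05 with limma), 5 and 90, APAP against AMAP 28 at 6 h and 314 at 24 h, control 60 and 123, and the APAP effect 1 (24 against 6 h). Trend and robust variances gave 6 for the latter and quantile normalization 7. Array weights gave APAP 329 at 2 h and 3043 at 24 h, AMAP 58, 254 and 433, APAP against AMAP 132, 394 and 1501, control 894 (24 against 2 h), the APAP effect 297, 13 (24 against 6 h) and 1 (6 against 2 h), and the AMAP effect 2.

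Genes with a mean log2 of at least 6 alone gave AMAP 139 at 6 h and 260 at 24 h, control 401 (24 against 2 h), the APAP effect 115, 6 and 1, and a correlation between compounds of 0.617 at 6 h. A minimum of 8 gave control 494 (24 against 2 h) and the APAP effect 147 and 11. All probe sets gave AMAP 16, 43 and 79, APAP against AMAP 99 at 2 h, control 65 (24 against 2 h) and the APAP effect 27 (24 against 2 h). A 2-fold minimum left APAP 17, 19 and 37, AMAP 0 (1356 at an unadjusted p under 0.05 with limma), 1 and 5, APAP against AMAP 16, 10 and 41, control 8 and 7, and the APAP effect 5 and 1. The block within each time gave APAP 418, 1112 and 3141, AMAP 101, 473 and 727, and APAP against AMAP 128, 301 and 1896. It gave the APAP effect 447, 127 and 3, and the AMAP effect 29. For control it gave 67 (6 against 2 h) and 147 (24 against 2 h). A block set within each time does not cancel when control is compared between times. These control counts are thus not comparable with those of the main model. Without the 6 h arrays of number 32, APAP gave 239 and AMAP 17 at 6 h, control 90 (6 against 2 h) and the APAP effect 5 (24 against 6 h). Without the 24 h APAP and AMAP arrays of number 31, APAP gave 1147, AMAP 61 and APAP against AMAP 511.

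Leaving out each number or single array gave ranges of 38 to 125, 65 to 348 and 449 to 1871 for APAP, 0 to 24, 5 to 84 and 10 to 103 for AMAP, and 20 to 80, 18 to 167 and 195 to 809 for APAP against AMAP at 2, 6 and 24 h. For control the ranges were 17 to 101 (6 against 2 h) and 12 to 194 (24 against 2 h), for the APAP effect 0 to 66 (24 against 2 h), 0 to 4 (24 against 6 h) and 0 to 1 (6 against 2 h), and for the AMAP effect 0 to 0. The correlation between compounds ranged from 0.397 to 0.578 at 2 h, 0.559 to 0.598 at 6 h and 0.414 to 0.538 at 24 h.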

Other observations

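Other fixed gene lists held called genes with APAP at 24 h, and none of the 6 that follow was called with an estimated correlation. Of 32 proteasome genes 5 fell and 0 rose, 14 and 0 adjusted over the list alone (median -0.23, camera adjusted p = 3.43e-08, adjusted p = 0.427 with an estimated correlation), led by Psma5 (-0.50 ± 0.11). Of 25 ATF4 targets 8 fell and 3 rose, 11 and 3 adjusted over the list alone; Sesn2 (0.96 ± 0.16), the phosphatase subunit Ppp1r15a (1.11 ± 0.19) and Ddit3 (0.87 ± 0.16) rose and the serine synthesis enzyme Psph (-0.53 ± 0.12) fell, with adjusted p = 0.611 with an estimated correlation. Of 17 cytosolic heat shock genes 4 fell, among them the cochaperones Fkbp4 (-0.62 ± 0.09) and Ahsa1 (-0.49 ± 0.13), and 1 rose, 6 and 1 adjusted over the list alone, with adjusted p = 0.427 with an estimated correlation. Of 16 circadian clock genes 5 rose and 1 fell, 6 and 1 adjusted over the list alone; the nuclear receptor Nr1d1 rose by 0.87 ± 0.12 and Bhlhe40 fell by 0.65, with adjusted p = 0.427 with an estimated correlation. Of 21 genes of autophagy and lysosomes 4 rose, 5 higher and 1 lower adjusted over the list alone, led by cathepsin D (Ctsd, 0.32 ± 0.07), with adjusted p = 0.427 with an estimated correlation. Of 24 genes of hypoxia and glycolysis 5 fell, among them Tpi1 (-0.44 ± 0.10), and 1 rose, 9 and 2 adjusted over the list alone, with camera adjusted p = 0.0531 and adjusted p = 0.427 with an estimated correlation.

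Apoptosis regulators changed in both directions with APAP at 24 h. Of 29 members of the BCL2 family and caspases, Pmaip1 (0.76 ± 0.10) and the apoptosome component Apaf1 (0.56 ± 0.11) rose and Bok (-0.86 ± 0.10) and Bid (-0.48 ± 0.10) fell, also adjusted over the list alone (camera adjusted p = 0.718). The same list held Bok as its 1 called gene for AMAP at 24 h (-0.43 ± 0.10), and the compounds differed for Bok by -0.43 ± 0.10 (adjusted p = 0.0144). Among markers of other cell types, Pdgfra (-0.41 ± 0.10) and Vim (-0.24 ± 0.07) of 20 fibroblast and stellate cell markers fell with APAP at 24 h, also adjusted over the list alone, with camera adjusted p = 0.888. Of the genes named in this part, Sesn2, Fkbp4, Nr1d1, Bok and Pmaip1 kept their calls with APAP without each number in turn, and the others lost them without at least 1 number.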
